A study of Mus musculus with 4 samples.

How the data were processed

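RNA was measured in 4 libraries of the mouse cell line BEKO, 2 from cells at low density and 2 from cells at high density. Per the labels' protocols, RNA was isolated with a column kit for small samples and made into strand-specific libraries by a commercial provider. The samples are described as total RNA. Whether ribosomal RNA was removed or polyadenylated RNA selected is not given in the sources used here.

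The authors deposited a single table of TPM values, transcript abundances scaled to a fixed total, with 25630 rows, 1 column per library and each column summing to 1000000. The submitters' processing notes name the genome build mm9 and DESeq2 version 1.2.10 without saying what either was used for. The aligner, the counter, the gene annotation and the gene lengths behind the TPM are not given in the sources used here. Each column was tied to its sample by the column name in that sample's description. TPM keeps no depth, so the number of reads per library is unknown, and no counting interval or detection limit is given. TPM is also relative: a rise of abundant RNAs in a library lowers the values of the others. Length enters TPM as a divisor, so values of very short rows, such as small nucleolar RNAs, depend strongly on the length used and on how fragments of that size were kept.

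Rows are named by gene symbol in the table, apart from 699 Ensembl identifiers. All 699 were matched to a symbol through a table of mouse gene names. The reference annotation at hand is of another mouse build, so no coordinates are given. It was used for symbols, for transcript length and GC content, and to find which gene holds which small nucleolar RNA. No mitochondrially encoded gene is among the rows, and these genes were not analysed here.

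All tests used log2(TPM + 1), so a log2 fold change is on the scale of log2(TPM + 1) and understates the change of weakly expressed genes. Rows with a mean of at least 1 TPM over the 4 libraries were tested, 10936 in number, and 14694 rows lay below that filter. High density was compared with low density with limma 3.58.1 in R 4.3.3 (a linear model per row with a group term, moderated variances and a mean-variance trend, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all rows tested. A row was called at an adjusted p under 0.05. The model has 2 residual degrees of freedom, to which the moderation added 9.53. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so no such test is reported.

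Before the data were examined, 36 gene lists were fixed for T cell receptor signalling, T cell programmes, the cell cycle, growth, metabolism, stress and markers of other cell types. The 31 lists with at least 5 rows tested were compared with all other rows by camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the residuals and fry, which tests whether the members of a list move on balance in 1 direction, were run beside it. Members were also counted after their p-values had been adjusted over the list alone. Counts of members refer to those that passed the filter. The genes to be named were set by rule: the 14 largest rises and 14 largest falls among called rows with a mean of at least 5 TPM, no overlap between the groups and a gene symbol that is not a predicted model; up to 4 members of smallest p from each list described; and 19 genes chosen for the subject of the series. Some genes set by these rules are not reported here, though they stay in the list tests. Where a list had few called members, further ones are named as well, and those outside the rule were picked after their values were seen. In each comparison "higher" means higher at high density.

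Limma and camera were tested on simulated data made from the means and spread of these libraries. Changes were placed only in rows above 10 TPM at low density, and both groups were given the same spread. The rates found do not cover weaker rows or the wider spread between the high density libraries. In 10 simulations with 200 changed genes among 10609 to 10646 tested, 19.9% of 2-fold changes and 94.5% of 4-fold changes were called, 0 with the wrong sign, and 3.11% of calls were false. Camera called 10 of 10 lists made to shift and 0 of 200 unchanged lists. With an estimated correlation it called 0 of the 10 shifted lists, so that form of the test had no power at this size. Noise was drawn independently for each gene, so neither result covers lists whose genes vary together. In the libraries the estimated correlation was 0.68 for hypoxia, 0.60 for glycolysis, 0.56 for ribosome biogenesis and 0.99 for cholesterol synthesis.

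Alternatives fixed before the data were examined were another pseudocount (0.1 or 5), another filter (none, or a mean of at least 5 TPM), centring of each library on its median, quantile normalisation, rescaling without ribosomal protein genes, limma without the trend or with robust moderation, the replicate number as a block, and leaving out each library in turn. 4 further alternatives were chosen after the data were seen. Rows with near-identical copies elsewhere in the genome, such as Gapdh, Eno1, Rpl27, Rpl34 and Rps23, are uncertain, because how the counter treated reads shared between copies is not known. The same holds for microRNA and small nucleolar RNA rows inside longer genes. T cell receptor rows of a locus are not independent measurements.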

Results

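RNA was sequenced from BEKO, a mouse thymic lymphoma cell line, at low and at high cell density, with 2 libraries in each group. The labels give no cell number, medium or culture time for either density. Nothing in them says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The title of the series concerns γδ T cells and the IL-17 receptor chain IL17RA, and genes of these subjects were therefore examined beside lists for growth, metabolism and stress. Values are TPM as mean ± SD with n = 2 libraries per group unless stated, and fold changes without a log are ratios of mean TPM. Where a library is left out, its group holds a lone library, and calls rest on the spread of the other group. The low density pair was the tighter, so more rows were called without a high density library.

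Of the 25630 rows, 15553 were above 0 in low density library 1, against 13892 in low density library 2, 13605 in high density library 1 and 13758 in high density library 2. Across genes, log2 values correlated at r = 0.983 between the low density libraries, at 0.961 between the high density libraries and at 0.935 to 0.941 between groups. The first principal component held 61.8% of the variance and separated the densities. The second held 27.1% and separated the high density libraries from each other. The pooled SD of log2 values was 0.28 between the low density and 0.43 between the high density libraries. In low density library 1, 35 rows reached 5 TPM that lay under 0.5 TPM in the other 3 libraries, against 0, 1 and 2 such rows in the other libraries.

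Relative to all RNA in the table, called genes of the hypoxia response (20 of 24) and of glycolysis (14 of 19) were higher at high density, and called genes of ribosome biogenesis (13 of 31, and 1 without low density library 2) were lower. Camera called these 3 lists with its preset correlation, but not with an estimated one (adjusted p = 0.613, 0.647 and 0.613). Bnip3, a mitochondrial receptor for autophagy induced by low oxygen, rose 58.0-fold (93.0-fold without low density library 1), and Vegfa, the vascular growth factor, rose 56.1-fold (95.3-fold without low density library 1 and 35.9-fold without high density library 1). Rag1 and Rag2, the recombinase genes of developing lymphocytes, fell 2.97-fold and 3.06-fold, but the Rag2 call was lost without low density library 1 (limma adjusted p = 0.254) and without low density library 2 (0.148). RNA of the receptor gene Il17ra was 74.2 ± 5.32 TPM at low and 104 ± 22.9 TPM at high density. It did not pass the test (log2 fold change 0.47 ± 0.25 SE, limma adjusted p = 0.288). The ratio of mean TPM was 1.19 without high density library 1 and 1.62 without high density library 2.

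Among the 10936 rows tested, 731 were called by limma, 500 higher and 231 lower at high density, so that 68.4% of calls were higher. Without the filter on low values limma called 0 rows (2638 at an unadjusted p under 0.05). At least a 2-fold change was found for 471 of the higher and 187 of the lower rows. In all 731 the 2 groups did not overlap, and over all rows tested 54.7% had no overlap, where chance gives 33.3%. The median log2 fold change of all rows tested was 0.12, and changes are to be read against that shift. This shift depended on high density library 2: it was 0.27 without high density library 1 and −0.023 without high density library 2. The median log2 value of tested rows was 5.05 and 4.94 in the low density libraries. It was 5.02 in high density library 1 and 5.34 in high density library 2. The excess of higher calls is therefore not to be read as an effect of density alone. With each library centred on its median the calls were 160 higher and 154 lower (51.0% higher), and after quantile normalisation 60.0% of calls were higher. Leaving out 1 library gave between 233 calls, without low density library 2, and 3270, without high density library 1. Of 31 lists tested, camera called 8 higher and 9 lower. With an estimated correlation 0 lists were called (lowest adjusted p = 0.613, and 0 at an unadjusted p under 0.05). Fry called 0, with 9 lists at an unadjusted p under 0.05.

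**Figure D1:**
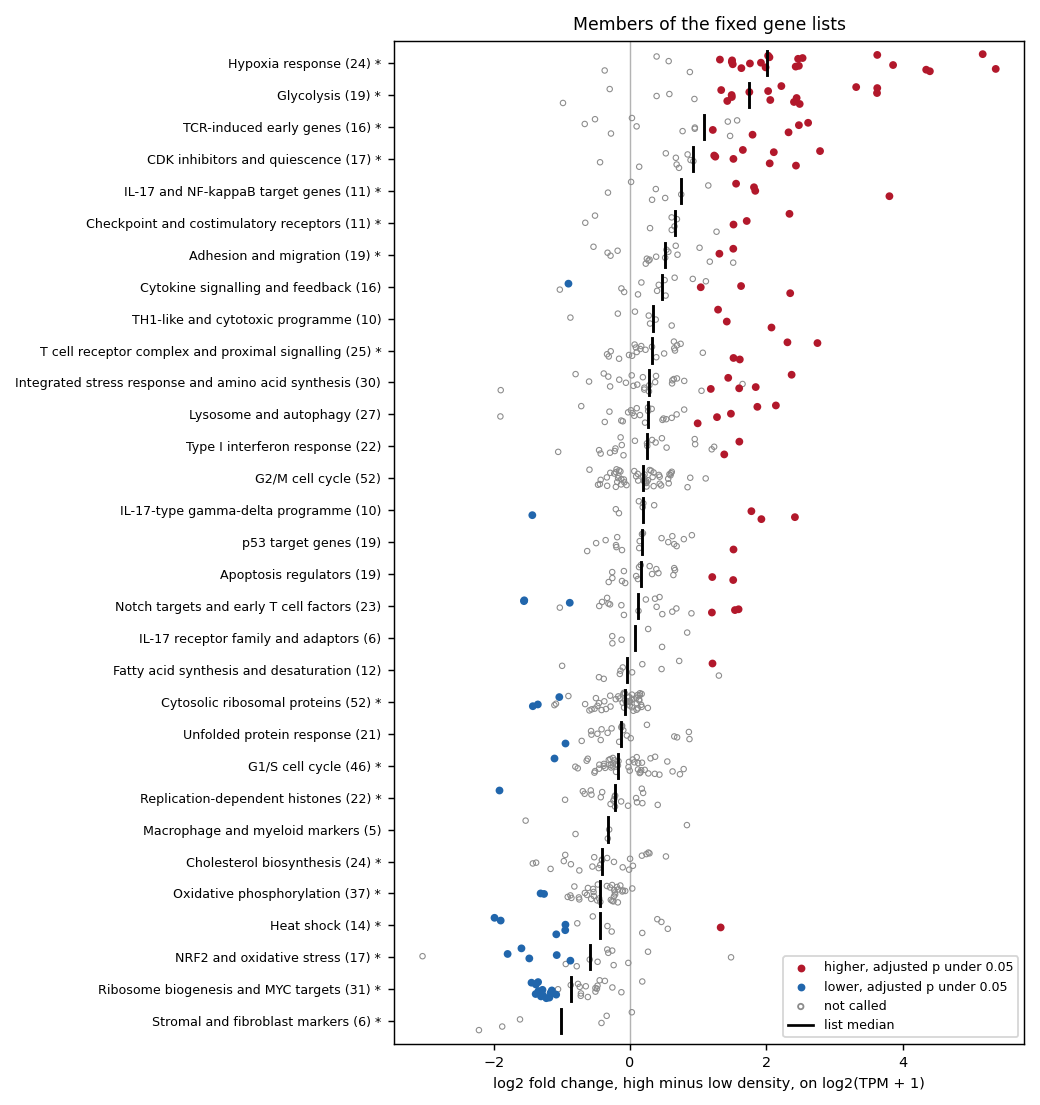
Log2 fold change on log2(TPM + 1) of the tested members of 31 gene lists, high minus low density, with the number of members in parentheses and an asterisk where camera called the list. Red and blue points are called members, open circles are members not called and bars are list medians, from 2.01 for the hypoxia response to −1.02 for stromal markers, whose members were not called.

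Hypoxia-response genes rose at high density in 20 of 24 tested members, with 0 lower and a median log2 fold change of 2.01. The same number, 20, rose when adjusted over the list alone. Camera called the list (adjusted p = 2.34e-17; adjusted p = 0.613 with an estimated correlation). Bnip3 went from 2.38 ± 1.27 to 138 ± 50.5 TPM, and Vegfa from 1.91 ± 1.11 to 107 ± 54.6 TPM. Ankrd37, a known target of hypoxia-inducible factor, rose 23.8-fold (15.7-fold without high density library 1), and Bhlhe40, a transcriptional repressor of the circadian system, rose 24.5-fold. Ero1l, the oxidase that drives disulfide formation in the endoplasmic reticulum, rose 18.2-fold, from 33.1 ± 1.99 to 602 ± 488 TPM (7.75-fold without high density library 1 and 28.6-fold without high density library 2).

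Genes of glycolysis rose in 14 of 19 tested members, with 0 lower and a median log2 fold change of 1.75 (16 higher when adjusted over the list alone). The camera adjusted p was 4.73e-09, and the adjusted p was 0.647 with an estimated correlation. The glucose transporter genes Slc2a3 and Slc2a1 rose 11.6-fold and 14.5-fold, Pfkp, a phosphofructokinase, rose 15.3-fold, from 12.1 ± 2.74 to 185 ± 135 TPM, and Hk2, the inducible hexokinase, rose 5.85-fold. Without high density library 1 the rise was 7.67-fold for Slc2a1 and 7.41-fold for Pfkp, and without high density library 2 it was 23.1-fold for Pfkp. Pfkfb3, Pfkfb4, Slc2a1, Pgk1 and Ldha belong to both lists. Without these 5 genes the camera adjusted p was 1.24e-15 for hypoxia and 4.67e-07 for glycolysis. Both medians were higher in high density library 1 (2.25 and 2.30) than in high density library 2 (1.56 and 1.24). After median centring, 9 hypoxia and 3 glycolysis members were called. After quantile normalisation 15 and 9 were called, and 11 and 5 with length and GC content removed, an alternative chosen after the data were seen. The list medians under these 3 settings were 1.82, 2.01 and 1.88 for hypoxia and 1.56, 1.67 and 1.73 for glycolysis, and camera called both lists under each (highest adjusted p = 3.24e-06). Ldha, Gapdh, Pkm and Narf lost their calls without either low density library, with rises then between 2.37-fold and 3.37-fold. Fam162a lost its call without low density library 1, and Pfkl and Mxi1 lost theirs without low density library 2.

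**Figure D2:**
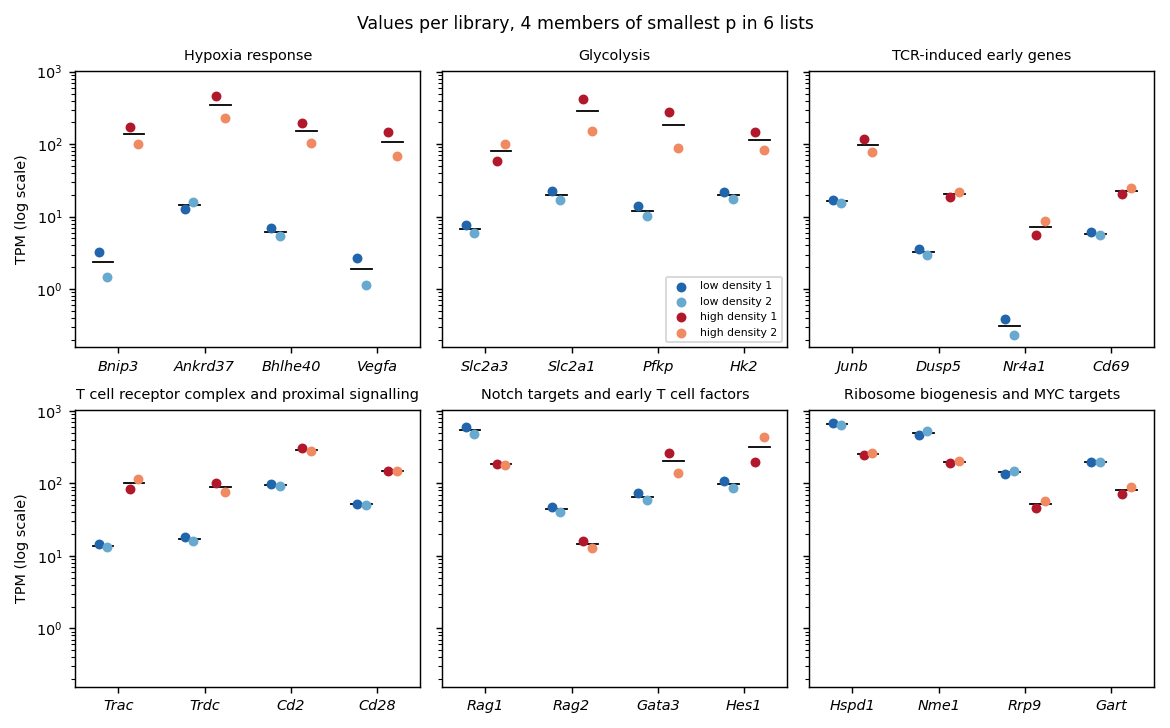
TPM on a log axis in each of the 4 libraries for the 4 members of smallest p in 6 lists, with bars at group means. Bnip3 rises from 2.38 to 138 TPM and Hspd1 falls from 669 to 256 TPM, and for each gene shown both high density libraries lie on the same side of both low density libraries.

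Several large rises lay outside these lists. Hdac5, a class IIa histone deacetylase, rose 37.7-fold, from 1.65 ± 0.665 to 62.1 ± 2.92 TPM. Maff, a small Maf transcription factor, rose 60.8-fold from 0.594 ± 0.0257 TPM, and Gsn, the actin-severing protein gelsolin, rose 19.8-fold (36.5-fold and 11.3-fold without high density library 1). Cox6a2, the muscle-type form of a cytochrome c oxidase subunit, rose 11.2-fold (24.0-fold and 7.33-fold without low density library 1 or 2, and 6.56-fold without high density library 2). Eif4e3, a cap-binding protein, rose from 6.03 ± 1.57 to 84.2 ± 58.1 TPM, and Bex6 from 0.11 ± 0.156 to 10.3 ± 1.94 TPM. The rise of Eif4e3 was 7.15-fold without high density library 1 and 20.8-fold without high density library 2.

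Genes that T cell receptor signalling induces early were higher at high density as a list, with 5 of 16 tested members called and a median log2 fold change of 1.08 (10 higher when adjusted over the list alone). The camera adjusted p was 0.000599, and the adjusted p was 0.613 with an estimated correlation. The called members were Junb, an AP-1 subunit, up 5.96-fold, Dusp5, a phosphatase of ERK, up 6.25-fold, the nuclear receptor Nr4a1, the activation marker Cd69 and the early gene Ier2. Nr4a1 went from 0.308 ± 0.105 to 7.13 ± 2.16 TPM (limma adjusted p = 0.00304) and Cd69 from 5.84 ± 0.32 to 22.9 ± 3.1 TPM (limma adjusted p = 0.0049). Cd5, an inhibitor of receptor signalling, had a log2 fold change of 1.47 ± 0.41 (SE) with a limma adjusted p of 0.053, and Id3, an antagonist of E proteins, one of 0.77 ± 0.26 with 0.0984. Both passed when adjusted over the list alone. Cd5 was called by limma without the trend (adjusted p = 0.0195) and with robust moderation (0.0441). Cd5 was weakly expressed, at 0.34 ± 0.211 TPM at low and 2.69 ± 0.37 TPM at high density. Without high density library 1 or 2 the rise was 7.15-fold and 8.69-fold for Cd5 and 1.82-fold and 1.57-fold for Id3. Without low density library 1 or 2 it was 5.50-fold and 14.1-fold for Cd5 and 1.45-fold and 2.05-fold for Id3. Leaving out either low density library gave 3 higher members, without Cd69 (limma adjusted p = 0.0947 without library 1 and 0.139 without library 2) and Ier2 (0.314 and 0.536), leaving out high density library 1 gave 9 with 1 lower, and leaving out high density library 2 gave 8. Egr1, Egr2 and Egr3, immediate early transcription factors, lay below the filter, with mean TPM of 0.749, 0.131 and 0.00983 at low and 0.789, 0.311 and 0.00978 at high density.

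In the list for the T cell receptor complex and its proximal signalling, 4 of 25 members rose, 8 when adjusted over the list alone, and the median log2 fold change was 0.32 (camera adjusted p = 0.0204; adjusted p = 0.662 with an estimated correlation). These were the receptor constant regions Trac, up 7.22-fold, and Trdc, from 17.1 ± 1.47 to 89.3 ± 17.3 TPM, the adhesion molecule Cd2, up 3.08-fold, and the costimulator Cd28, up 2.90-fold. Cd3e, an invariant chain of the complex, had a log2 fold change of −0.31 ± 0.23 (SE, limma adjusted p = 0.456). Without high density library 1 the camera call on this list was lost (adjusted p = 0.53), with 10 members higher and 1 lower, and without high density library 2 there were 9 higher. Cd28 lost its call without low density library 2 (limma adjusted p = 0.0556).

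Checkpoint and costimulatory receptors were called higher (camera adjusted p = 0.0181; adjusted p = 0.613 with an estimated correlation), with 3 of 11 members up: Ctla4, an inhibitory receptor, 3.36-fold, Cd28, and Vsir, which encodes the inhibitory receptor VISTA, 7.80-fold. The count was also 3 when adjusted over the list alone. Adhesion and migration genes were called higher as a list (camera adjusted p = 0.0219; adjusted p = 0.662 with an estimated correlation), with 2 of 19 members up, the integrins Itgb3 and Itgae, and 5 when adjusted over the list alone. Neither list was called without high density library 1 (adjusted p = 0.0583 and 0.289). The adhesion list was also not called without low density library 2 (0.0894), and the checkpoint list not after rescaling without ribosomal protein genes (0.0646). The checkpoint count was 1 without low density library 2, where Ctla4 and Cd28 lost their calls (limma adjusted p = 0.0907 and 0.0556), and 6 without high density library 1. The adhesion count was 0 without low density library 1 (limma adjusted p = 0.12 for Itgb3 and 0.423 for Itgae) or 2 (0.333 and 0.344), after median centring, after quantile normalisation and with length and GC content removed, 5 without high density library 2, and 8 with 1 lower without high density library 1. It was also 1 after rescaling without ribosomal protein genes, 4 at a mean of at least 5 TPM, and 5 with robust moderation, without small non-coding RNA rows and without the rows of low density library 1 alone.

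Notch targets and early T cell factors moved both ways, with 3 of 23 members higher and 3 lower (5 and 4 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.564). Its median was 0.12 while camera placed it lower. The median was −0.015 without low density library 2 and 0.26 without low density library 1. Gata3, a master regulator of T cell development, rose 3.07-fold, the Notch target Hes1 rose 3.27-fold (2.01-fold without high density library 2), and Cd8b1, a coreceptor chain, rose 2.34-fold. Rag1 fell from 545 ± 91 to 183 ± 2.36 TPM and Rag2 from 44.1 ± 5.03 to 14.4 ± 2.22 TPM. Nrarp, a feedback inhibitor of Notch, fell as well (log2 fold change −0.88 ± 0.23 SE). There was 1 lower member without low density library 1, and there were 0 higher and 1 lower without low density library 2, 5 higher without high density library 1, and 7 higher and 5 lower without high density library 2. Calls were lost without low density library 1 for Rag2, Cd8b1 and Nrarp (limma adjusted p = 0.254, 0.12 and 0.41), and without low density library 2 for these genes (0.148, 0.38 and 0.654), Gata3 (0.106) and Hes1 (0.0907). After median centring, after quantile normalisation and with length and GC content removed, 1 was higher.

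Of the IL-17 receptor family and its adaptors, 0 of 6 tested members were called, also when adjusted over the list alone, and the list median was 0.07 (camera adjusted p = 0.886). There was 1 higher and 1 lower member without high density library 1, and 2 were higher without high density library 2. Traf3ip2, the adaptor Act1, was 19 ± 1.85 TPM at low and 34.6 ± 0.305 TPM at high density (limma adjusted p = 0.0816). Its log2 fold change was 0.83 without high density library 1 and 0.85 without high density library 2. Of 27 genes in the list for targets of IL-17 and NF-κB, only 11 passed the filter. The list was called higher (camera adjusted p = 0.00141, and adjusted p = 0.613 with an estimated correlation), with 4 of the 11 up and 6 when adjusted over the list alone. The 4 were the cytokine gene Ltb, up 17.8-fold to 83.7 ± 41.6 TPM (11.6-fold without high density library 1), and Nfkbia, Nfkbiz and Tnfaip3, 3 regulators of NF-κB that it also induces, up 3.66-fold, 4.78-fold and 3.10-fold. Nfkbiz and Tnfaip3 lost their calls without low density library 1 (limma adjusted p = 0.133 and 0.0721) and without low density library 2 (0.084 and 0.458). The count of higher members was 1 after median centring, 2 after quantile normalisation, without either low density library and with length and GC content removed, and 7 without high density library 1.

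The TH1-like and cytotoxic list was not called (camera adjusted p = 0.173), but was called higher without low density library 1 (0.0309). Over all libraries 3 of 10 members were higher. Gzma, a granzyme of cytotoxic cells, rose from 276 ± 24.1 to 771 ± 310 TPM, the chemokine gene Ccl5 rose from 0.0681 ± 0.0962 to 3.74 ± 2.17 TPM and Stat4, which acts downstream of IL-12, rose from 13.9 ± 4.46 to 34.7 ± 3.49 TPM. Adjusted over the list alone, 3 were higher and 1 lower. The counts were 0 higher and 1 lower after median centring and with length and GC content removed, and 1 and 1 after quantile normalisation. Stat4 lost its call without low density library 1 (limma adjusted p = 0.145). Without low density library 2 there was 1 higher member, as Stat4 and Gzma lost theirs (0.703 and 0.104), and without high density library 1 or 2 there was 1 lower member beside the higher ones. Tbx21, the TH1 master regulator, lay below the filter at 0.145 and 0.175 TPM, and Ifng was listed at 0 in all 4 libraries.

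The list for IL-17-type γδ T cells was not called either (camera adjusted p = 0.239), with 3 of 10 members higher and 1 lower, the same counts when adjusted over the list alone. Etv5, an ETS transcription factor, rose 7.14-fold, Rora, an orphan nuclear receptor, rose 4.97-fold, and 5830411N06Rik rose from 0.0595 and 0.146 TPM to 2.96 and 3.43 TPM. Il7r, the IL-7 receptor chain, fell 2.83-fold, and without low density library 1 or 2 its call was lost (limma adjusted p = 0.496 and 0.178), as was that of Rora without low density library 2 (0.221). After median centring, after quantile normalisation and with length and GC content removed, 1 was higher and 0 lower, and 0 were lower after rescaling without ribosomal protein genes. Sox13, a transcription factor of IL-17-producing γδ cells, had a log2 fold change of 0.19 ± 0.33 (SE, limma adjusted p = 0.78). Zbtb16, the factor PLZF, was at 0.152 TPM in low density library 1 and listed at 0 in the other 3 libraries, and Il17a was listed at 0 in all 4.

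Cytokine signalling genes were not called as a list (camera adjusted p = 0.121). The kinase gene Pim1 and the receptor genes Il10ra and Il6st rose, and Socs1, a feedback inhibitor, fell (log2 fold change −0.90 ± 0.24 SE), which makes 3 higher and 1 lower of 16 (5 and 2 when adjusted over the list alone). Without high density library 2 the list was called higher (camera adjusted p = 0.013), with 8 members higher and 2 lower. The lower count was 0 without either low density library and by limma without the trend, and the higher count was 1 without low density library 2, after median centring, after quantile normalisation and with length and GC content removed. The type I interferon response was not called (camera adjusted p = 0.399), with 2 of 22 members higher, the RNA sensor Ddx58 and the antiviral gene Rsad2, and 3 when adjusted over the list alone. The higher count was 0 without low density library 2, after median centring and after quantile normalisation, 1 with length and GC content removed, after rescaling without ribosomal protein genes and with a pseudocount of 5, and 6 without high density library 2, and 2 were lower without high density library 1. The calls of Il6st, Socs1 and Ddx58 were lost without low density library 1 (limma adjusted p = 0.431, 0.507 and 0.228), and without low density library 2 these (0.619, 0.453 and 0.536) and those of Pim1 (0.253) and Rsad2 (0.234).

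Genes of ribosome biogenesis and other MYC targets were lower at high density in 13 of 31 members, with 0 higher and 30 of the 31 below 0. The median log2 fold change was −0.87 (−1.26 in high density library 1 and −0.56 in high density library 2), and 21 fell when adjusted over the list alone. The camera adjusted p was 3.26e-15, and the adjusted p was 0.613 with an estimated correlation. Hspd1, the mitochondrial chaperonin, fell from 669 ± 34.4 to 256 ± 9.45 TPM, and Nme1, a nucleoside diphosphate kinase, from 500 ± 44.8 to 196 ± 6.97 TPM. Rrp9, a small nucleolar ribonucleoprotein subunit, and Gart, a purine synthesis enzyme, fell by 1.45 and 1.28 on the log2 scale. Myc itself was at 231 ± 26.9 TPM at low and at 141 and 315 TPM in the high density libraries (limma adjusted p = 0.852). It was called lower without high density library 2 (log2 fold change −0.70, adjusted p = 0.0305) and had a log2 fold change of 0.45 without high density library 1 (adjusted p = 0.0988). Leaving out 1 library moved the count of lower members to 4 without low density library 1, 1 without low density library 2 and 29, with 1 higher, without high density library 2. Gart lost its call without low density library 1 (limma adjusted p = 0.0961), and Nme1, Rrp9 and Gart without low density library 2 (0.12, 0.144 and 0.144).

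Genes of cell cycle arrest and quiescence were higher in 8 of 17 members, with 0 lower and a median of 0.93 (13 when adjusted over the list alone; camera adjusted p = 7.46e-07; adjusted p = 0.613 with an estimated correlation). Txnip, an inhibitor of glucose uptake, rose 7.10-fold, Cdkn1b, the cyclin-dependent kinase inhibitor p27, 4.29-fold, Tsc22d3, the glucocorticoid-induced GILZ, 4.20-fold, and Ccng2, an atypical cyclin, 6.16-fold (3.31-fold without high density library 1). The count was 3 after median centring and with length and GC content removed, 4 after quantile normalisation or without low density library 2, and 13 without high density library 1 (with 1 lower) or 2. Cdkn1a, the inhibitor p21, was at 49.9 and 43.6 TPM in the low and at 136 and 41.7 TPM in the high density libraries (limma adjusted p = 0.366). Its log2 fold change was −0.16 without high density library 1 and 1.53 without high density library 2.

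Few proliferation genes were called. Of 52 G2/M genes 0 were called, also when adjusted over the list alone (camera adjusted p = 0.886). The high density libraries stood apart here: camera called the G2/M list lower without high density library 1 (median −0.18, adjusted p = 5.66e-05, 2 members higher and 12 lower) and higher without high density library 2 (median 0.38, adjusted p = 4.52e-05, 10 higher). Mki67, the proliferation marker, had a log2 fold change of 0.42 ± 0.23 (SE, limma adjusted p = 0.296). In the G1/S list 1 of 46 members fell, the uracil glycosylase gene Ung, 1 also when adjusted over the list alone. The list was called lower with a median of −0.17 (camera adjusted p = 0.0204; adjusted p = 0.757 with an estimated correlation), but its median was −0.32 in high density library 1 and 0.12 in high density library 2. Replication-dependent histones were called lower with a median of −0.23 (−0.11 in high density library 1 and −0.41 in high density library 2). The camera adjusted p was 0.00505, and the adjusted p was 0.613 with an estimated correlation. Of 22 members 1 fell, Hist2h2ac, 1 also when adjusted over the list alone. The G1/S call was lost after quantile normalisation (adjusted p = 0.182), without low density library 2 (0.103) and without high density library 1 (0.327), and the histone call without high density library 2 (0.461) and with length and GC content removed (0.168). In G1/S 0 members fell without either low density library, Ung having limma adjusted p-values of 0.314 and 0.343, 3 fell and 9 rose without high density library 1, and 9 fell without high density library 2. At a mean of at least 5 TPM, with robust moderation, with length and GC content removed and with either set of rows left out, 2 fell. Among histones 0 fell without low density library 1 (Hist2h2ac, 0.103), 4 fell without high density library 1, and 1 rose without high density library 2.

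Oxidative phosphorylation genes were lower as a list with a median of −0.44, and 36 of 37 members lay below 0 (camera adjusted p = 9.64e-09; adjusted p = 0.613 with an estimated correlation). The complex I subunit gene Ndufa5 and Ndufa4, which encodes a subunit of cytochrome c oxidase, were the 2 called members, falling by 1.31 and 1.26 on the log2 scale, and 6 fell when adjusted over the list alone. The count was 0 without low density library 2 (limma adjusted p = 0.347 for Ndufa5 and 0.291 for Ndufa4), 11 without high density library 1 and 8 without high density library 2, and 1 after median centring, after quantile normalisation, by limma without the trend and with length and GC content removed. It was 5 at a mean of at least 5 TPM, and 4 with robust moderation and with either set of rows left out. Cytosolic ribosomal protein genes had a median of −0.07 and were called lower (camera adjusted p = 0.000599; adjusted p = 0.662 with an estimated correlation). Of 52 members 3 fell, Rpl27, Rpl34 and Rps23, the same number when adjusted over the list alone, and these have near-identical copies that make their values uncertain. The summed TPM of the ribosomal protein list was 103506 and 120398 at low and 122485 and 101068 at high density. The ribosomal protein call was lost after quantile normalisation (adjusted p = 0.157), without high density library 2 (0.425, median 0.02), without low density library 2 (0.0985) and with length and GC content removed (0.0943). The count of lower members was 0 without low density library 1 (limma adjusted p = 0.0583 for Rpl27, 0.193 for Rpl34 and 0.11 for Rps23) or 2 (0.231, 0.656 and 0.718), 8 without high density library 1, 7 without high density library 2 and 5 at a mean of at least 5 TPM, and 1 after median centring, after quantile normalisation and with length and GC content removed.

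Heat shock genes were called lower (camera adjusted p = 0.00784; adjusted p = 0.662 with an estimated correlation), with 5 of 14 members lower and 1 higher (6 and 1 when adjusted over the list alone). The chaperone genes Hsph1 and Hspa8 fell 4.09-fold and 3.36-fold (6.13-fold for Hspa8 without high density library 1), Ahsa1, an activator of HSP90, fell 2.12-fold, and Dnajb4, a co-chaperone, rose 2.73-fold. Genes of the NRF2 and oxidative stress response were lower in 5 of 17 members with a median of −0.59 (−0.49 in high density library 1 and −0.90 in high density library 2). The camera adjusted p was 1.48e-05, and the adjusted p was 0.662 with an estimated correlation. Adjusted over the list alone 8 were lower and 1 higher. Txnrd1, thioredoxin reductase, fell 3.02-fold, Prdx1, a peroxiredoxin, 3.24-fold (5.19-fold without high density library 1), Gstm1, a glutathione transferase, 2.77-fold (4.23-fold without that library) and Pgd, an enzyme of the pentose phosphate pathway, 2.06-fold. Neither call held without high density library 2 (adjusted p = 0.153 and 0.103). In the NRF2 list the lower count was 1 after median centring, after quantile normalisation and without low density library 2, 2 with length and GC content removed, 3 without low density library 1, after rescaling without ribosomal protein genes and by limma without the trend, and 11 without high density library 1, and 1 was higher without high density library 2 and at a mean of at least 5 TPM. In the heat shock list it was 2 without either low density library and 3 after median centring, after quantile normalisation, with length and GC content removed and by limma without the trend, each with 0 higher. Rescaling without ribosomal protein genes also left 0 higher, and 2 were higher without high density library 1. Calls were lost without low density library 1 for Ahsa1, Dnajb4, Gstm1 and Pgd (limma adjusted p = 0.195, 0.218, 0.162 and 0.198), and without low density library 2 for the same genes (0.197, 0.505, 0.447 and 0.456) and Txnrd1 (0.0516).

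Cholesterol synthesis genes differed between the high density libraries. Their median against the low density mean was 0.49 in high density library 1 and −1.34 in high density library 2, and summed TPM was 3844 and 2843 at low and 4777 and 1532 at high density. Of 24 members 0 were called, also when adjusted over the list alone, while camera called the list lower with a median of −0.41 (adjusted p = 0.0156; adjusted p = 0.738 with an estimated correlation) and called it higher without high density library 2 (adjusted p = 0.00634). Of the members 18 were lower without high density library 1, and 6 were higher without high density library 2. At a mean of at least 5 TPM 2 were lower, and with either small non-coding RNA rows or the rows of low density library 1 alone left out 1 was lower. The call was lost after median centring (adjusted p = 0.22), after quantile normalisation (0.182), without a filter on low values (0.116) and with length and GC content removed (0.19). In the fatty acid list, which was not called (camera adjusted p = 0.886) but was called lower without high density library 1 (0.0305), the desaturase gene Scd2 rose 2.33-fold, the only called member of 12. Adjusted over the list alone, 2 were higher and 1 lower, and the list's median of −0.04 and mean of 0.14 differed in sign. The higher count was 0 without low density library 2, after median centring, after quantile normalisation, after rescaling without ribosomal protein genes, by limma without the trend and with length and GC content removed, 2 with 1 lower at a mean of at least 5 TPM, and 3 without high density library 2, and 2 were lower without high density library 1. The adjusted p of Scd2 was 0.481 without low density library 2.

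**Figure D3:**
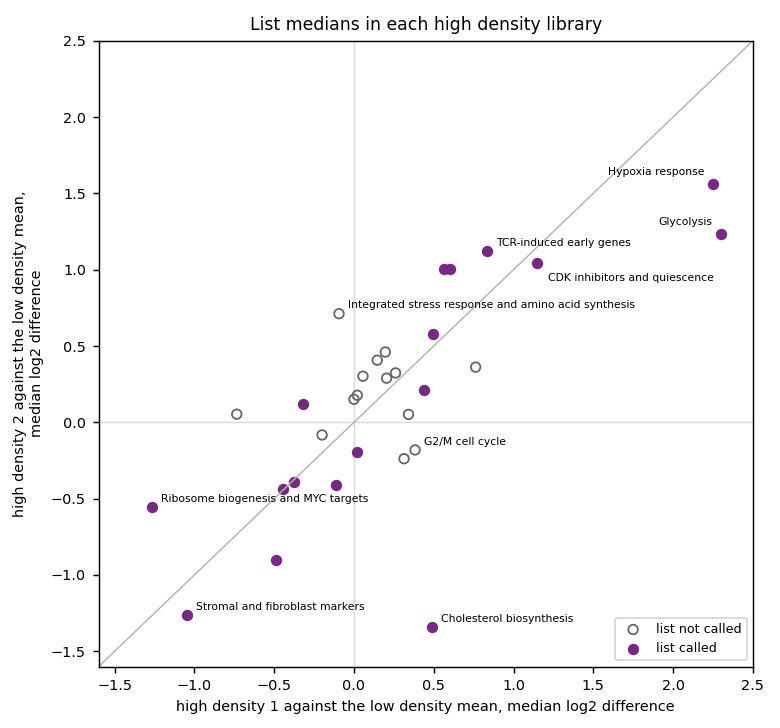
Median log2 difference of each tested gene list from the low density mean, in high density library 1 (horizontal axis) and in high density library 2 (vertical axis), with filled points for lists that camera called. Hypoxia response lies at 2.25 and 1.56, and cholesterol biosynthesis at 0.49 and −1.34, away from the diagonal of equal values.

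The lists for other stress responses were not called with all 4 libraries under the main settings. In the integrated stress response 5 of 30 members rose, 7 when adjusted over the list alone (camera adjusted p = 0.162): Trib3, a pseudokinase, 5.72-fold (9.75-fold without low density library 1), Ddit3, the factor CHOP, 2.98-fold, and Slc6a9, Fgf21 and Cebpg. The median of this list was −0.09 in high density library 1 and 0.71 in high density library 2, and camera called it higher without high density library 1 (adjusted p = 0.0287), without low density library 1 (0.00431) or after quantile normalisation (0.0221). The higher count was 0 with 1 lower without low density library 2, 14 with 1 lower without high density library 1, and 2 after median centring, after quantile normalisation and with length and GC content removed, and 3 were lower without high density library 2. In the unfolded protein response Calr, a chaperone of the endoplasmic reticulum, was the 1 member of 21 that fell (camera adjusted p = 0.0889), with 2 higher and 1 lower when adjusted over the list alone. This list was called lower at a mean of at least 5 TPM (0.0482) and without high density library 1 (0.0136). It had 0 lower members without either low density library, after median centring, after quantile normalisation, after rescaling without ribosomal protein genes, by limma without the trend and with length and GC content removed, 2 higher at a mean of at least 5 TPM, with robust moderation and without small non-coding RNA rows, 3 higher and 3 lower without high density library 1, and 2 higher and 5 lower without high density library 2. Bbc3, the cell death gene PUMA, rose 2.89-fold and was the 1 called gene of 19 in the p53 list, 1 also when adjusted over the list alone (camera adjusted p = 0.564). With Bcl2l11, the cell death gene BIM, it made 2 higher of 19 among apoptosis regulators, 2 also when adjusted over the list alone (camera adjusted p = 0.318). The higher counts of the p53 and the apoptosis list were 0 and 0 without low density library 2, 1 and 1 without low density library 1, 3 (with 1 lower) and 4 without high density library 1, 6 (with 2 lower) and 5 without high density library 2, and 0 and 1 after median centring and after quantile normalisation. Lysosome and autophagy genes were higher in 5 of 27 members, 5 also when adjusted over the list alone, without a call for the list (camera adjusted p = 0.113): Wipi1, an autophagy protein, 6.55-fold, Tfeb, a regulator of lysosome genes, 4.32-fold, and Fnip1 and Atg9a were among them. This list was called higher without low density library 1 (0.0451), without high density library 2 (0.00202) and at a mean of at least 5 TPM (0.0482). The higher count was 2 without low density library 1, 1 without low density library 2, 8 without high density library 1 or 2, 2 after median centring and after quantile normalisation and 3 with length and GC content removed. Without low density library 2 and without high density library 1 or 2, 1 member was lower. The calls of Cebpg, Calr, Bcl2l11, Fnip1 and Atg9a were lost without low density library 1 (limma adjusted p from 0.0955 to 0.429), and without low density library 2 these and the calls of Trib3, Ddit3, Slc6a9, Fgf21, Bbc3 and Tfeb (0.0967 to 0.663).

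The largest falls were in short non-coding RNAs. Rpph1, the RNA of RNase P, fell 56.9-fold, from 156 ± 86.5 to 2.74 ± 1.15 TPM (34.6-fold without low density library 1). Rmrp, the related RNA of RNase MRP, was at 58.7 and 3.15 TPM in the low and at 1.14 and 0 TPM in the high density libraries (limma adjusted p = 0.0442). The small nucleolar RNAs Snora44, Snord87, Snord88c and Snord12 fell 5.40-fold, 4.91-fold (9.46-fold without high density library 1), 4.94-fold (7.67-fold without high density library 2) and 4.18-fold, and Snhg3, a host gene of small nucleolar RNAs, fell 3.82-fold. The row of the microRNA Mir1949 fell 7.65-fold, 32.9-fold without high density library 1 and 4.33-fold without high density library 2. The interferon-inducible genes Ifi204 and Ifi211 fell 4.75-fold and 3.77-fold (7.47-fold for Ifi211 without high density library 1), Fam163b 4.13-fold and Hist2h2ac, a histone H2A gene, 5.49-fold (9.01-fold without high density library 2). Snora44, Snord88c, Snord12 and Ifi211 lost theirs without low density library 2 (limma adjusted p = 0.0524, 0.0796, 0.088 and 0.0906), Snord87 and Hist2h2ac without low density library 1 (0.0853 and 0.103) and Rmrp without high density library 2 (0.103). Of all called rows of small non-coding RNAs, 36 were lower and 12 higher. Small nucleolar RNAs made up 28 of the lower and 2 of the higher rows. The remaining higher rows were microRNA rows, so the fall of Mir1949 does not stand for microRNA rows in general.

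Few markers of other cell types passed the filter. Of B cell markers 1 passed the filter, of dendritic cell and MHC class II genes 2, of erythroid markers 3 and of epithelial markers 2, and 0 of these were called over all rows. Cd74, the invariant chain of MHC class II, was at 12.7 ± 1.33 TPM at low and 5.22 ± 0.187 TPM at high density (limma adjusted p = 0.0501, and under 0.05 without high density library 1 or 2, at 0.0123 and 0.0113, and after median centring or quantile normalisation, at 0.0479 and 0.0387), and the class II list had 1 lower member when adjusted over the list alone. Of 5 macrophage markers 0 were called (camera adjusted p = 0.173), but without low density library 2 the list was called lower (0.0296) with 1 lower member. Without high density library 1 there was 1 lower member, and without high density library 2 there was 1 higher and 1 lower. The stromal list, in which 0 of 6 members were called, was lower by camera with a median of −1.02 (adjusted p = 0.0204; adjusted p = 0.662 with an estimated correlation), and without low density library 1 its median was −0.11 and the call was lost (adjusted p = 0.466). It was also lost without high density library 2 (0.425), after median centring (0.11), after quantile normalisation (0.157) and with length and GC content removed (0.111). Of its members 3 were lower without low density library 2, 1 was lower without high density library 1 and 1 was higher without high density library 2. The collagen gene Col1a1 was at 30.3 TPM in low density library 1, listed at 0 in low density library 2 and at 0.172 and 0.236 TPM in the high density libraries. Col1a2 and Sparc, other matrix genes, stood out in the same library at 14.5 and 7.45 TPM. Without low density library 2 these 3 genes were called lower (highest adjusted p = 3.41e-05). By contrast, Thy1, Pecam1 and Vim were expressed in every library.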

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

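The alternatives without small non-coding RNA rows, without rows of low density library 1 alone, with length and GC content removed, and with the genes shared by 2 lists left out were chosen only after the result was seen; all others were fixed beforehand. The depth of the libraries is unknown, and with 2 libraries per group a single library decides many calls. Leaving out 1 library leaves its group with a lone library, assumed to vary like the other group, which is tighter at low than at high density.

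Rows called were 731 in all, 500 higher and 231 lower, 471 and 187 of them by at least 2-fold. Without a filter limma called 0 rows in either direction, 0 by at least 2-fold, with 2638 at an unadjusted p under 0.05; many more rows near 0 were then tested, and the cause was not tested further. Median centring gave 314 (160 higher, 152 of them by at least 2-fold, and 154 lower), quantile normalisation 360 (216 higher, 202 by at least 2-fold, and 144 lower), and removal of length and GC content 444 (250 higher, 211 by at least 2-fold). Limma without the trend called 144 lower. The cause was not tested. Leaving out 1 library gave 233 to 3270 calls: 145 to 2525 higher (145 to 1069 by at least 2-fold) and 86 to 1193 lower (86 to 495 by at least 2-fold), with the fewest after a low density and the most after a high density library was left out. The remaining settings (both pseudocounts, the stricter filter, rescaling without ribosomal protein genes, robust moderation, the replicate block and both row removals) stayed within 1.5 times of these counts. Without small non-coding RNA rows 869 rows were called, and without the rows of low density library 1 alone 845.

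With the replicate number as a block, 937 rows and 16 lists were called, and the G1/S list was lost (adjusted p = 0.075). Counts of called members moved, among others, for cholesterol biosynthesis (0 to 6 lower), stromal markers (0 to 3 lower), adhesion (2 to 5 higher), early genes of T cell receptor signalling (5 to 8 higher) and oxidative phosphorylation (2 to 4 lower). The labels give no meaning to the number. The deviations of the libraries numbered 1 correlated at 0.04, a single value that neither shows nor excludes a shared origin.

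Lists called were 17, and 13 to 19 under every other setting apart from camera with an estimated correlation (0) and fry (0). With length and GC content removed 4 of the 17 were lost: replication-dependent histones (adjusted p = 0.168), cholesterol biosynthesis (0.19), cytosolic ribosomal proteins (0.0943) and stromal markers (0.111). Without a filter 1 was lost, cholesterol biosynthesis (0.116). The self-test with an estimated correlation called 0 shifted lists as well, but its genes varied independently, so it does not cover lists whose genes vary together. Among 93 called genes named, calls lost were 25 without low density library 1, 47 without low density library 2, 0 or 1 without a high density library, 43 after median centring, 36 after quantile normalisation, 40 with length and GC content removed and all 93 without a filter. Limma without the trend and rescaling without ribosomal protein genes lost 10 each, robust moderation 5, a pseudocount of 5 lost 4, and a pseudocount of 0.1 and the replicate block lost 1 each. Those lost without low density library 1 or 2 include Rag2 (adjusted p = 0.254 and 0.148), Cd69 (0.0947 and 0.139) and Il7r (0.496 and 0.178).

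In called rows the groups did not overlap, so leaving out 1 library could not reverse a sign. Under the other settings no called gene changed sign either. Of the called lists, cholesterol biosynthesis did, with medians of −1.34 to 0.49 when 1 library was left out. Lists that were not called turned the direction of their test, with these medians: IL-17 receptor family −0.072 (quantile), −0.17 (length and GC) and −0.021 to 0.18 (1 library left out); Notch targets 0.10 (quantile) and 0.12 (fry); G2/M 0.20 (replicate block) and −0.18 to 0.38; fatty acid synthesis −0.057 (quantile), −0.039 (fry) and −0.24 to 0.31; interferon response 0.19 to 0.32, p53 targets 0.13 to 0.29 and lysosome 0.052 to 0.35 (1 library left out). Genes that were not called and changed sign were Cldn4 (−0.15 centred, −0.058 quantile, −0.0078 length and GC, −0.071 to 0.14 with 1 library left out) and Sox13 (−0.0012 centred, −0.0094 quantile, −0.28 to 0.65). With 1 library left out, Myc ran from −0.70 (adjusted p = 0.0305) to 0.45 (0.0988), Cdkn1a from −0.16 to 1.53, Traf6 from −0.043 to 0.57, Il17rb from −0.60 to 0.085, Apoe from −0.71 to 0.054, Ccl25 from −0.35 to 0.29 and Col1a1 from −4.70 to 0.27. The cause was not tested.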

Other observations

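All tests in this part were chosen only after the result was seen, apart from the comparison of small nucleolar RNAs with their host genes and the test of sequencing depth, whose bounds were written before their results were known.

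Gene groups beside the fixed lists were collected after the data had been seen, so their counts describe these libraries and are no independent test. Some members were already in the fixed lists: Kdm3a and Bhlhe40 in the hypoxia list and Rora in the IL-17-type γδ list. Of 6 tested GTPase genes of the GIMAP family, which act in the survival of lymphocytes, 4 were higher at high density: Gimap1 (30 ± 2.66 to 104 ± 15.3 TPM), Gimap7 (1.21 ± 0.305 to 14.1 ± 5.27 TPM), Gimap8 and Gimap9. Of 20 genes of the Jumonji family, 8 were higher, among them Kdm3a, up 3.92-fold, Jmjd6, up 3.23-fold, and Kdm4b, up 3.10-fold. The count was 5 without low density library 1, 2 without low density library 2, 13 without high density library 1 and 9 with 2 lower without high density library 2. Of 12 genes of glycogen metabolism 5 were higher, with Gys1, the glycogen synthase, up 3.77-fold and Pgm2 up 5.80-fold, but 1 without low density library 2. Among 18 genes of the circadian clock 5 were higher: Bhlhe40, Ciart (11.3-fold, and 6.44-fold without high density library 1), Dbp (5.80-fold), Per1 (4.13-fold) and Rora. Of the 8 subunits of the chaperonin CCT 7 lay below 0 and 1, Cct3, was called lower (566 ± 1.06 to 306 ± 39 TPM). Leaving out low density library 2 left 2 higher GIMAP and 3 higher clock genes, and the clock count was 10 without high density library 1 and 8 without high density library 2. For CCT the lower count was 0 without either low density library, 5 without high density library 1 and 3 without high density library 2. Calls were lost without low density library 1 for Gimap9 and Cct3 (limma adjusted p = 0.367 and 0.334), and without low density library 2 for these (0.322 and 0.47), Gimap8 (0.0723), Kdm4b (0.108), Gys1 (0.094), Per1 (0.0667) and Rora (0.221). With an estimated correlation the adjusted p of these 5 groups lay between 0.168 and 0.254 over the 9 groups collected in this way.

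Rows of the T cell receptor alpha and delta locus rose together at high density. Of 41 tested rows 30 were higher and 0 lower, with a median log2 fold change of 2.16, and their summed TPM was 131 and 118 at low and 905 and 685 at high density (adjusted p = 0.168 with an estimated correlation). Most called rows were joining segments such as Traj6, listed at 0 in both low density libraries and at a mean of 13 ± 0.464 TPM at high density. Such rows passed the filter only through the high density libraries, so the count and the median favour rises. The summed TPM covers all 200 rows of the locus, tested or not. The gamma locus had 0 of 12 rows called and the beta locus 1 of 9, lower. In the gamma locus 10 rows were higher without high density library 2 and 2 were lower without high density library 1. In the beta locus 2 were lower without low density library 1 and without high density library 1 or 2. The alpha and delta count ran from 26 (with 1 lower, without low density library 2) to 35 (with 1 lower, without high density library 2). Rows of a locus overlap and are read from shared transcripts, so they are not independent.

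Genomic DNA in the high density libraries would have raised silent gene families too. The summed TPM of 1454 olfactory and vomeronasal receptor rows was at most 1.03 times as high in a high as in a low density library, which argues against it. T cells of another clone cannot be told apart by these rows. The median log2 fold change of the beta locus was −0.32 (0.029 without high density library 1), but 7 of its 9 rows had a mean under 5 TPM and γδ T cells need not carry beta transcripts. The gamma locus had summed TPM of 4825 and 4350 already at low density, which could hide those of a further clone. Higher transcription of the locus in the high density cells stays open as well and was not tested. Rag1 and Rag2 fell in the same libraries.

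Small nucleolar RNA rows were lower at high density in 28 and higher in 2 of 94 tested, with a median of −0.90 (adjusted p = 0.168 with an estimated correlation). The calls depend on single libraries: 16 were lower and 1 higher without low density library 1, 3 and 0 without low density library 2, 54 and 6 without high density library 1, and 38 and 7 without high density library 2. The median then ran from −1.07 to −0.69. Reads of the host gene counted to these rows would have given both the same change, if such reads follow the host row. Reads from introns were not measured apart, so the comparison cannot decide on host reads from there. Over 86 rows with a tested host the median difference, row minus host, was −0.96 (95% bootstrap interval −1.14 to −0.64), and across rows the 2 changes were hardly related (Spearman rho = 0.04, permutation p = 0.74; rows are not independent replicates). A loss of all short features would have lowered other rows under 300 nt. Their median was 0.13 (−0.13 to 0.30) without T cell receptor rows and 0.32 with them. These rows include microRNA rows, which may hold reads of longer genes, so their median cannot decide on a loss of short RNAs. That explanation stays open. A lower yield of RNAs of just this size class may also account for the pattern. So may lower amounts of small nucleolar RNAs beside the fall of ribosome biogenesis genes, and neither was tested.

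Low density library 1 held rows that the other libraries lacked: 35 rows at 5 TPM or more there and under 0.5 TPM elsewhere, adding up to 412 TPM. Deeper sequencing of this library would need the others to miss such rows by chance. Of rows that lay between 5 and 30.3 TPM in both remaining libraries, low density library 2 missed (under 0.5 TPM) 0.489%, high density library 1 missed 0.0813% and high density library 2 missed 0.141%. With the upper bounds of the 95% binomial intervals of these shares, only 0.000318 rows of the 3617 in that range in low density library 1 would on average be missed by all 3, if they miss rows independently, which argues against depth. RNA or reads from another tissue may be the source: 19 of 69 markers of nerve, matrix, muscle, liver, epithelium and blood reached 1 TPM in this library alone, 7 of them neural and 5 stromal, against 0 in each other library. The most abundant were Col1a1 (30.3 TPM), Ckb (24.8), Uchl1 (23.3), Cpe (21.3) and Snap25 (20.7), some of which had been seen before the marker list was written. Low density itself would have raised these rows in low density library 2 too. Of 39 rows at 5 TPM or more in low density library 1 and under 0.5 TPM at high density, picked without regard to low density library 2, 10.3% (95% binomial interval 2.87% to 24.2%; rows are not independent) reached 1 TPM there, which argues against a state shared by both low density libraries as the source of most of these rows. The bound used, an interval wholly under 50%, was written after the share was seen, in place of a first bound of under 10% that had been missed by 1 row. Whether the low density cultures differed in density is not given and stays open.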
